A study of Mus musculus with 43 samples.

How the data were processed

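RNA of 43 mouse mammary tumours was measured by RNA sequencing. RNA was extracted with a Qiagen RNeasy kit and libraries were made with NEBNext reagents, per the labels' protocols. The deposited values are FPKM, that is, fragments scaled by transcript length and by the mapped fragments of the library. Per the submitters' processing notes, the authors used TopHat and Cufflinks with the mouse build mm9. The versions of these tools, the annotation, the read counts and the strand setting are not given in the sources used here. The table holds 21529 genes with an Ensembl identifier each, of which 21505 were above 0 in at least 1 library. Gene symbols were taken from the table, where 25 had been turned into dates by a spreadsheet. All 25 were named again by their Ensembl identifier from a GENCODE M21 gene table of the build GRCm38. No coordinate is printed, because that build is not the one the authors used. Another 25 entries had no symbol and 77 shared a symbol with another entry.

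Samples were grouped by their titles and tissue labels. The groups were Pik (3 tumours with no virus named), shCdkn2a, shPten and shTsc22d1 (3 tumours each, a lentivirus for knockdown of 1 gene) and pool (31 tumours, a lentivirus pool). Replicate numbers come from the titles. The labels do not say whether the replicates of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

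FPKM holds no depth, and Cufflinks assigns fragments between transcripts, so that whole reads could not be recovered. The depth of each library is therefore unknown, no counting interval is given, and a value of 0 is reported as listed at 0. FPKM is relative to all mapped fragments of a library, so a few very abundant transcripts lower the values of all other genes. Total FPKM per library was 354617 to 840481 in the pool and 373001 to 436025 in the other groups.

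Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Genes needed 1 FPKM or more in at least 3 libraries of the fit. The 4 groups of 3 were fitted together (12 libraries, 8 residual degrees of freedom, 13397 genes), and the pool was fitted with Pik (34 libraries, 32 residual degrees of freedom, 14487 genes). Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Targeted genes were also compared with an exact two-sided permutation test. Tables were read with data.table (version 1.17.8). Correlations were computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

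The tests, the groups, 33 lists of genes (434 genes, 432 of them measured, without Mzb1 and Hmgcs1) and the rule for naming genes were fixed before the data were examined. The lists cover mammary cell types, other cell types a tumour can hold, cell cycle, metabolism and signalling. Each list was tested with camera of limma at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry, adjusted over the 33 lists. The text names Pik3ca, Cdkn2a, Pten, Tsc22d1, Cdkn2b and Trp53 in each comparison. It names the 10 genes per direction with the largest change against Pik among those passing the threshold, with a mean of 5 FPKM or more in the higher group and no overlap between the 3 and 3 libraries. For the pool at least 28 of the 31 tumours had to lie on 1 side of the Pik mean. Predicted genes, pseudogenes and small RNA genes were left out of that part of the rule. For a list it names up to 4 passing members with the largest change, or up to 2 with the smallest p where none passed. Between single-virus groups it names 5 genes per direction, and in the pool the 20 genes with the largest spread. Some of the genes that qualified are given only as part of a count.

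The pool tumours were clustered by average linkage on 1 minus Pearson's r over the 2000 most variable genes. Within each of the 2 clusters, 8 pairs of list scores (mean z-score of the members) and 3 scores of the genes that differed between a single-virus group and Pik, with the gene named in its label, were correlated, with 100000 permutations (two-sided, smallest possible p = 1e-05) and again without the 2 tumours farthest from the median. The distance between 2 libraries is the SD of their difference in log2(FPKM + 1) over 8900 genes with a mean of 5 FPKM or more.

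The fit and the list test were checked on simulated data in which 100 genes were changed by a factor of 2 and 100 by a factor of 4. For shCdkn2a against Pik (13063 genes) 55% and 81% of these were recovered, for shPten (13069 genes) 54% and 75%, for shTsc22d1 (13020 genes) 49% and 80%, and for the pool (15005 genes) 27% and 75%. Calls among unchanged genes numbered 11, 5, 7 and 6. These shares and calls hold for the simulated data only. In the real data the groups were of unequal spread, with libraries at most 0.187 apart in shPten and up to 1.81 apart in shTsc22d1. The share of false calls in the real comparisons is therefore not known from the simulation. For the list test the check was only that a list of genes raised on purpose passed. Simulated genes varied independently, so it does not show how the list test behaves for genes that vary together.

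Alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, quantile normalization, a robust fit, all 43 libraries in 1 fit, only the 2 groups compared, the replicate number as a block, and each library of a group of 3 left out in turn. Where an arm then had fewer libraries, its spread was taken from the whole fit. Added after seeing the data were fits without the 5 single-virus libraries that held almost no keratin RNA, without the 17 pool libraries of the second cluster, without pool tumours 20 and 21, and with GC content regressed out of each library, and the list test for shPten with the 2 groups alone. GC content came from the GENCODE M21 transcripts and was known for 98.6% of the tested genes. The clusters were also a choice made after seeing the data. Counting tests were not used, because the table holds no counts.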

Results

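The series holds RNA profiles of 43 mammary tumours from mice with a mutant Pik3ca allele, which encodes the catalytic subunit of a PI3 kinase. Of these, 3 tumours (Pik) carried no named virus. Another 9 came from glands given a lentivirus for knockdown of Cdkn2a, Pten or Tsc22d1 (3 each), and 31 (pool) came from glands given a pool of lentiviruses for lesions found in patients. The question is which transcripts differ between tumours with an added lesion and tumours with the mutant Pik3ca allele alone. The depth of the libraries is unknown, because the deposited values are FPKM. Genes at 1 FPKM or more numbered 11568 to 12521 in the 12 libraries outside the pool and 9114 to 20088 in the pool. In pool tumour 20 only 3.01% of genes were at 0, against 22.7% to 26.5% in the 12 libraries outside the pool, and its most abundant entry was the predicted gene Gm10800 at 28992 FPKM. In pool tumour 21 the 4 most abundant genes, led by the secretory gland transcript Abpa at 189150 FPKM, made up 67.5% of the total.

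The targeted genes were examined first. Cdkn2a (ENSMUSG00000044303), which encodes a cyclin-dependent kinase inhibitor and the Arf protein, was at 7.74, 4.95 and 6.71 FPKM in the shCdkn2a libraries and at 52.0, 104 and 25.3 in Pik. The means were 6.47 ± 1.41 and 60.4 ± 39.9 FPKM (SD, n = 3 each), a log2 fold change of -2.84 (SE 0.53, limma adjusted p = 0.00293). These 3 libraries also held lymphoid RNA and almost no keratin RNA, and Cdkn2a was at 0.706 to 17.7 FPKM in the pool tumours of the lymphoid (second) cluster against 12.9 to 73.6 in the keratin-rich cluster. Pten (ENSMUSG00000013663), the phosphatase that opposes PI3 kinase, was at 6.47, 6.80 and 6.23 FPKM in the libraries labelled shPten and at 6.87, 5.17 and 5.62 in Pik. At the level of RNA these libraries go against their label, since Pten was not lower than in Pik. Protein was not measured. Its means were 6.50 ± 0.286 and 5.89 ± 0.883 FPKM (SD, n = 3 each), a log2 difference of 0.13 with a 95% interval of -0.48 to 0.74 (limma adjusted p = 0.930). Tsc22d1 (ENSMUSG00000022010), a transcriptional regulator with a leucine zipper, was at 100, 23.3 and 18.7 FPKM in the libraries labelled shTsc22d1 and at 69.1, 77.5 and 90.6 in Pik. The log2 difference was -1.13 (95% interval -2.23 to -0.02, limma adjusted p = 0.0824). The library labelled shTsc22d1 1 goes against its label, with more Tsc22d1 than any Pik library, and without it the log2 fold change was -1.86 (limma adjusted p = 3.03e-07). The 2 libraries then left are lymphoid with almost no keratin RNA, and their Tsc22d1 lies inside its range in the second pool cluster (12.1 to 31.5 FPKM). Exact two-sided permutation tests gave p = 0.1 for Cdkn2a, p = 0.4 for Pten and p = 0.4 for Tsc22d1, where 0.1 is the smallest p that 3 against 3 allows. In the pool, Cdkn2a, Pten and Tsc22d1 were at 21.5 ± 17.4, 11.3 ± 4.49 and 57.7 ± 44.3 FPKM (SD, n = 31).

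**Figure D1:**
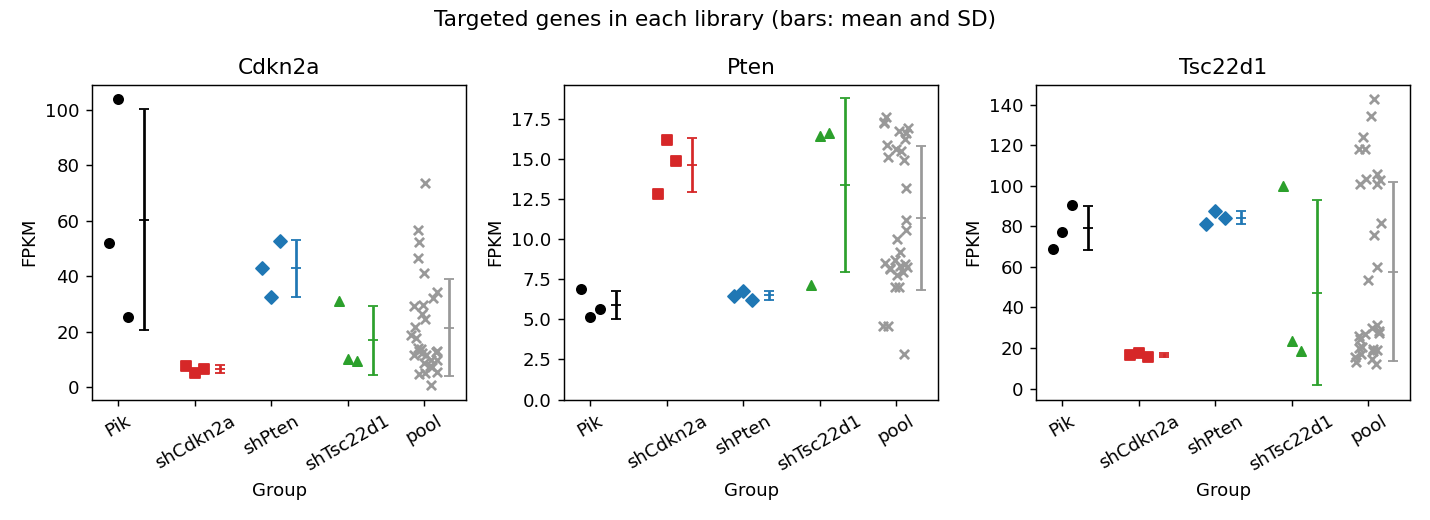
FPKM of Cdkn2a, Pten and Tsc22d1 in each of the 43 libraries, by group, with the mean and SD of each group as bars. Cdkn2a is low in all 3 shCdkn2a libraries (4.95 to 7.74 FPKM), Pten in the libraries labelled shPten (6.23 to 6.80 FPKM) lies within the range of Pik, and Tsc22d1 is at 100 FPKM in the library labelled shTsc22d1 1.

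Tumours given the Cdkn2a hairpin held RNA of B and T lymphocytes at high level and almost none of the keratins of mammary epithelium. Cd79a, a part of the B cell receptor, was at 1000 ± 14 FPKM against 0.853 ± 1.05 in Pik (SD, n = 3 each), a log2 fold change of 9.22 (SE 1.99, limma adjusted p = 0.00404). Krt8, a keratin of luminal cells, was at 3.38 ± 2.87 FPKM against 1575 ± 574 in Pik (SD, n = 3 each), a log2 fold change of -8.64 (SE 2.05, limma adjusted p = 0.00534). The other largest log2 rises were in the immunoglobulin genes Iglc2 (8.96), Iglc3 (8.83) and Ighg2c (8.65) and in the B cell genes Cd79b (8.62), Cd19 (8.45), Ms4a1 (8.25) and Faim3 (7.55). Glycam1 (8.37) and the B cell chemokine Cxcl13 (7.91) rose as well. The other largest log2 falls were in the keratins Krt15 (-8.11), Krt18 (-7.96), Krt19 (-7.93) and Krt5 (-7.77). They were joined by the secreted proteins Expi (-8.05), Lcn2 (-7.84) and Wfdc2 (-7.78), by Fam25c (-7.94) and by the tight junction claudin Cldn3 (-7.88). In all, 8984 of 13397 genes differed from Pik, 4560 higher and 4424 lower, and changes of more than 2-fold numbered 2335 and 2863. The 3 and 3 libraries did not overlap for 75.8% of genes, where chance gives 10% if all are separate tumours. With all 43 libraries in 1 fit the count was 3346. Of the 136 named genes that passed, 131 passed without each library in turn. The test takes the 3 libraries as separate tumours, but shCdkn2a 2 and 3 differed by only 0.149 (SD over genes of the log2 difference), less than any 2 of the 17 pool libraries of the second cluster described below (0.195 or more).

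Epithelial lists other than milk and alveolar were lower in shCdkn2a by camera at the preset correlation, and none passed with an estimated correlation. All 14 basal and myoepithelial genes fell, likewise 14 adjusted over the list alone (median log2 fold change -4.28, camera adjusted p = 0.000234). Among them were Krt14 (-7.25), the smooth muscle protein Cnn1 (-6.90) and Krt17 (-6.49). All 10 epithelial junction genes fell, likewise 10 adjusted over the list alone (median -5.03, camera adjusted p = 0.00163), with Cldn4 at -6.90 and the adhesion proteins Epcam and Cdh1 (E-cadherin) at -6.07 each. Of 11 luminal progenitor genes 10 fell, likewise 10 adjusted over the list alone (median -3.68, camera adjusted p = 0.00222), led by the transcription factors Sox10 (-6.49) and Elf5 (-4.77). Of 15 hormone-sensing luminal genes 11 fell and 2 rose, or 12 and 2 adjusted over the list alone (median -2.60, camera adjusted p = 0.0160), with Cited1 at -6.67. Of 9 squamous keratinization genes 7 fell and 1 rose, or 7 and 2 adjusted over the list alone (median -2.45, camera adjusted p = 0.0371), with Sprr1a at -4.20. For each of these 5 lists adjusted p = 0.565 with an estimated correlation. Of 8 milk and alveolar genes 6 fell and 1 rose, likewise adjusted over the list alone, and the list did not pass (camera adjusted p = 0.111). Its rising member was Glycam1, which high endothelial venules of lymph nodes also make, and the casein Csn3 fell by 7.09 on the log2 scale.

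The lymphocyte lists rose in the same libraries. All 9 B cell and plasma cell genes rose, likewise 9 adjusted over the list alone (median log2 fold change 7.19, camera adjusted p = 0.00222). Of 14 T and NK cell genes 13 rose, likewise 13 adjusted over the list alone (median 4.95, camera adjusted p = 0.00128), among them Cd2 (5.83), the kinase Lck (5.61) and the coreceptor chains Cd8b1 (5.79) and Cd8a (5.27). For both lists adjusted p = 0.565 with an estimated correlation. Of 19 PI3 kinase pathway members 8 rose and 7 fell, likewise adjusted over the list alone, and the list did not pass (median -0.10, mean 0.29, camera adjusted p = 0.932). The leukocyte subunit Pik3cd (4.28) and the leukocyte phosphatase Inpp5d (3.44) rose, and the regulatory subunit Pik3r1 (-2.49) fell. Of 12 antigen presentation genes 6 rose, likewise adjusted over the list alone (camera adjusted p = 0.0526), with the class II regulator Ciita at 3.66 and Cd74 at 2.38.

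Lists of other cell types did not pass in shCdkn2a. Of 8 neutrophil genes 4 rose, likewise adjusted over the list alone (camera adjusted p = 0.0623). Of 12 macrophage genes 7 fell and 1 rose, likewise adjusted over the list alone (camera adjusted p = 0.0726), the riser being the lysozyme Lyz2 (2.48). Lyz2 did not keep its call without each library in turn. Of 12 mesenchymal transition genes 5 fell and 2 rose, likewise adjusted over the list alone (camera adjusted p = 0.111), with the matrix protein Sparc at -4.16. Of 8 adipocyte genes 4 fell, likewise adjusted over the list alone (camera adjusted p = 0.196). Of 13 fibroblast and matrix genes 7 fell and 2 rose, likewise adjusted over the list alone (camera adjusted p = 0.327), with Thy1, which T cells also make, at 3.69. Of 10 endothelial genes 2 rose and 1 fell, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.718). Of 5 skeletal muscle genes 1 fell, likewise adjusted over the list alone (median 0.33, mean -0.58, camera adjusted p = 0.846). Of 5 red blood cell genes 0 passed with limma at both adjustments (camera adjusted p = 0.661).

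Cell cycle lists were higher in shCdkn2a, and hypoxia, stress and Notch lists were lower. Of 16 G1-S and replication genes 12 rose and 1 fell, likewise adjusted over the list alone (median log2 fold change 1.13, camera adjusted p = 0.00163, adjusted p = 0.565 with an estimated correlation), with the helicase subunit Mcm3 and the cyclin Ccne1 at 1.99 each. Of 14 mitosis genes 8 rose, likewise adjusted over the list alone (median 0.69, camera adjusted p = 0.0136, adjusted p = 0.567 with an estimated correlation), with Top2a at 1.57 and the proliferation marker Mki67 at 1.56. Of 17 glycolysis and hypoxia genes 15 fell, likewise adjusted over the list alone (median -2.27, camera adjusted p = 1.73e-05). Pik 1 and Pik 2 stand apart in that list (mean log2 of 7.20 and 7.07, against 5.79 in Pik 3). The prolyl hydroxylase Egln3 (-5.46), the carbonic anhydrase Car9 (-4.44) and the angiogenic factor Vegfa (-3.18) were among them. Of 12 immediate early and heat shock genes 10 fell and 1 rose, likewise adjusted over the list alone (median -2.48, camera adjusted p = 0.0114), with the heat shock gene Hspa1b at -5.45. Of 12 Notch genes 9 fell and 1 rose, likewise adjusted over the list alone (median -1.88, camera adjusted p = 0.0180), with the ligand Jag2 at -3.34. For these 3 lists adjusted p = 0.565 with an estimated correlation. Of 17 ribosomal protein genes 7 rose, or 4 adjusted over the list alone (median 0.42, camera adjusted p = 0.0371, adjusted p = 0.611 with an estimated correlation), with Rps24 at 1.22. The ribosomal list did not pass without shCdkn2a 1 (camera adjusted p = 0.0849), Pik 1 (camera adjusted p = 0.0562) or Pik 3 (camera adjusted p = 0.164), nor after quantile normalization (camera adjusted p = 0.144).

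Further lists held changed members in shCdkn2a without passing camera. Of 16 p53 target genes 10 fell and 3 rose, likewise adjusted over the list alone (camera adjusted p = 0.0678), with the desmosomal protein Perp at -7.31 and the cell cycle inhibitor Cdkn1a at -3.16. Of 15 TGF-beta target genes 9 fell and 3 rose, likewise adjusted over the list alone (camera adjusted p = 0.0678), with Ctgf at -5.97. Of 13 fatty acid synthesis genes 7 fell and 1 rose, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0526). Of 11 genes of senescence-associated secretion 5 fell and 2 rose, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.234). Of 11 Wnt genes 6 fell and 2 rose, likewise adjusted over the list alone (camera adjusted p = 0.250), the risers being the lymphocyte factors Tcf7 (4.74) and Lef1 (3.28). Of 15 cholesterol synthesis genes 6 rose and 2 fell, likewise adjusted over the list alone (camera adjusted p = 0.355). Of 3 TSC22 family genes 1 rose, likewise adjusted over the list alone (camera adjusted p = 0.402). Of 16 interferon response genes 6 rose and 3 fell, likewise adjusted over the list alone (camera adjusted p = 0.529). Of 16 FOXO target genes 5 rose and 6 fell, likewise adjusted over the list alone (camera adjusted p = 0.595).

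Among the genes given in each comparison, Tsc22d1 (log2 fold change -2.19, limma adjusted p = 0.00419) and Cdkn2b, the neighbour of Cdkn2a (-2.66, adjusted p = 0.00244), fell in shCdkn2a. Pten (1.18, limma adjusted p = 0.00448) and Pik3ca (1.26, adjusted p = 0.00286) rose, and Trp53 did not pass (0.22, adjusted p = 0.226). Cdkn2a in these libraries lay within its range of 0.706 to 17.7 FPKM in the 17 pool tumours of the second cluster described below (Krt8 at 103 FPKM or less, Cd79a at 24.9 or more).

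The libraries labelled shPten kept their epithelial keratins and differed from Pik in 279 genes, 160 higher and 119 lower. They lay 0.174 to 0.187 from each other (SD over genes of the log2 difference), closer than any 2 of the 14 keratin-rich pool tumours (0.320 or more) and than Pik 1 and Pik 2 (0.350). The test takes them as 3 separate tumours, which the labels do not state. The largest rises were in the growth factors Mdk and Areg. Midkine, Mdk, was at 80.8 ± 3.41 FPKM against 3.94 ± 3.17 (SD, n = 3 each), a log2 fold change of 4.26 (SE 0.68, limma adjusted p = 0.0136). Amphiregulin, Areg, a ligand of the EGF receptor, was at 109 ± 12.8 FPKM against 8.33 ± 7.89 (SD, n = 3 each), a log2 fold change of 3.95 (SE 0.57, limma adjusted p = 0.00838). The protease inhibitor Slpi fell from 160 ± 14.3 to 12.9 ± 4.92 FPKM (SD, n = 3 each), a log2 fold change of -3.59 (SE 0.31, limma adjusted p = 0.00186). The hypoxia-induced Ndufa4l2 fell from 183 ± 149 to 5.63 ± 0.60 FPKM (SD, n = 3 each), a log2 fold change of -4.02 (SE 0.85, limma adjusted p = 0.0439). Ndufa4l2 was at 227 and 305 FPKM in Pik 1 and Pik 2 but at 16.8 in Pik 3. Pten was not lower in these libraries, as given above, and none of the other genes given in each comparison passed. Their log2 differences were 0.37 for Trp53 (limma adjusted p = 0.290), 0.23 for Cdkn2b (adjusted p = 0.915), 0.10 for Tsc22d1 (adjusted p = 0.982), -0.15 for Pik3ca (adjusted p = 0.886) and -0.29 for Cdkn2a (adjusted p = 0.910).

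Other large log2 rises in the libraries labelled shPten were in the lipid receptor S1pr3 (2.67), the claudin Cldn6 (2.86), Rps4y2 (3.48), Tox2 (3.22), the peptide hormone gene Calca (2.84), Slc35f3 (2.81), Pcp4l1 (2.77) and Insc (2.69). Other large falls were in Ramp3, a partner of calcitonin family receptors (-2.96), the retinoic acid hydroxylase Cyp26a1 (-2.72), Barx2 (-3.84), the kallikreins Klk1b1 (-3.78) and Klk1b8 (-3.00), the oxidase Ero1l (-2.58), the immunoglobulin transporter Pigr (-2.56) and the hypoxia-induced Bnip3 (-2.53). Kallikreins form a family of near-identical genes, and Rps4y2 resembles Rps4x, so their values are uncertain where fragments were split between copies. The 3 and 3 libraries did not overlap for 33.5% of genes. Chance gives 10% only if all are separate tumours, and more if the libraries labelled shPten share a tumour. An unadjusted p under 0.05 was found for 1982 genes. The count of 279 changed with each library left out. It was 41, 36 and 53 without the libraries labelled shPten 1, 2 or 3, 121 and 135 without Pik 1 or Pik 2, and 415 without Pik 3. Of the 38 named genes that passed, 7 passed without each library in turn, namely Slpi, S1pr3, Ramp3, Fabp4, Scd1, Srebf2 and Cxcl5. The count was 5 with all 43 libraries in 1 fit, 1158 with the 2 groups alone and 1138 without the 5 single-virus libraries that held almost no keratin RNA.

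Lists of hypoxia, interferon response, senescence-associated secretion, myeloid cells and adipocytes were lower by camera in the libraries labelled shPten, with few single genes passing over all genes and no list passing with an estimated correlation. Of 17 glycolysis and hypoxia genes 5 fell over all genes and 14 adjusted over the list alone (median log2 fold change -1.15, camera adjusted p = 2.57e-13, adjusted p = 0.244 with an estimated correlation). The vasodilator peptide Adm (-2.50) and the glycolytic enzymes Pfkp (-1.31) and Pgk1 (-1.15) were among them, and the mean of the list was at 7.20 and 7.07 in Pik 1 and Pik 2 but at 5.79 in Pik 3. Of 16 interferon response genes 1 fell, Ifit3 (-1.25), and 3 adjusted over the list alone (median -0.61, camera adjusted p = 1.96e-06, adjusted p = 0.235 with an estimated correlation). Of 11 genes of senescence-associated secretion 3 fell, the chemokines Cxcl1 (-2.23) and Cxcl5 (-1.85) and the cytokine Il1b (-1.56). Adjusted over the list alone 3 fell and 1 rose (median -0.95, camera adjusted p = 0.00638, adjusted p = 0.235 with an estimated correlation). Of 12 macrophage genes 1 fell, the lysosomal Cd68 (-1.12), and 1 adjusted over the list alone (median -0.74, camera adjusted p = 0.000244, adjusted p = 0.418 with an estimated correlation). Of 8 neutrophil genes 0 passed over all genes with limma and 3 fell adjusted over the list alone (median -0.96, camera adjusted p = 0.00292, adjusted p = 0.587 with an estimated correlation). Of 8 adipocyte genes 1 fell, the fatty acid carrier Fabp4 (-2.28), and 2 adjusted over the list alone (median -0.90, camera adjusted p = 0.0151, adjusted p = 0.235 with an estimated correlation). Without Pik 3 the adipocyte list did not pass (camera adjusted p = 0.0563).

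Stress and ribosomal protein lists were also lower in the libraries labelled shPten, by 1 gene or none. Of 12 immediate early and heat shock genes 1 fell, the phosphatase Dusp1 (-1.26), and 1 adjusted over the list alone (median -0.81, camera adjusted p = 0.0108). Of 17 ribosomal protein genes 0 passed with limma at both adjustments (median -0.20, camera adjusted p = 0.00154). For both lists adjusted p = 0.587 with an estimated correlation, and without Pik 2 neither passed (camera adjusted p = 0.247 and camera adjusted p = 0.324).

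Lists of cholesterol synthesis, cell cycle, Wnt and hormone-sensing luminal genes were higher by camera, with at most 2 single genes each passing over all genes and no list passing with an estimated correlation. Of 15 cholesterol synthesis genes 1 rose over all genes, the sterol regulator Srebf2 (0.94), and 9 adjusted over the list alone (median log2 fold change 0.55, camera adjusted p = 4.57e-08, adjusted p = 0.237 with an estimated correlation). Of 16 G1-S and replication genes 1 rose, the helicase subunit Mcm6 (1.02), and 3 adjusted over the list alone (median 0.55, camera adjusted p = 1.46e-06, adjusted p = 0.418 with an estimated correlation). Of 14 mitosis genes 1 rose, the kinase Aurka (0.78), and 5 adjusted over the list alone (median 0.51, camera adjusted p = 3.82e-05, adjusted p = 0.556 with an estimated correlation). Of 11 Wnt genes 0 passed over all genes with limma and 2 rose adjusted over the list alone (median 0.78, camera adjusted p = 0.0105, adjusted p = 0.244 with an estimated correlation). Without Pik 3 the Wnt list did not pass (camera adjusted p = 0.158). Of 15 hormone-sensing luminal genes 2 rose, Areg and Ly6a (0.84), and 3 adjusted over the list alone (median 0.84, camera adjusted p = 0.0363, adjusted p = 0.674 with an estimated correlation). Its call was lost without the libraries labelled shPten 1, 2 or 3 (camera adjusted p = 0.0618, 0.101 and 0.118), without Pik 2 or Pik 3 (camera adjusted p = 0.0540 and 0.141), and with a pseudocount of 0.1 (camera adjusted p = 0.0699). The other 20 lists did not pass (camera adjusted p of 0.0939 to 0.962). Within them the lipid desaturase Scd1 (-1.83), the granzyme Gzma (-1.10) and the TGF-beta target Id2 (-1.27) fell, and the TGF-beta target Id3 rose by 1.5 on the log2 scale.

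**Figure D2:**
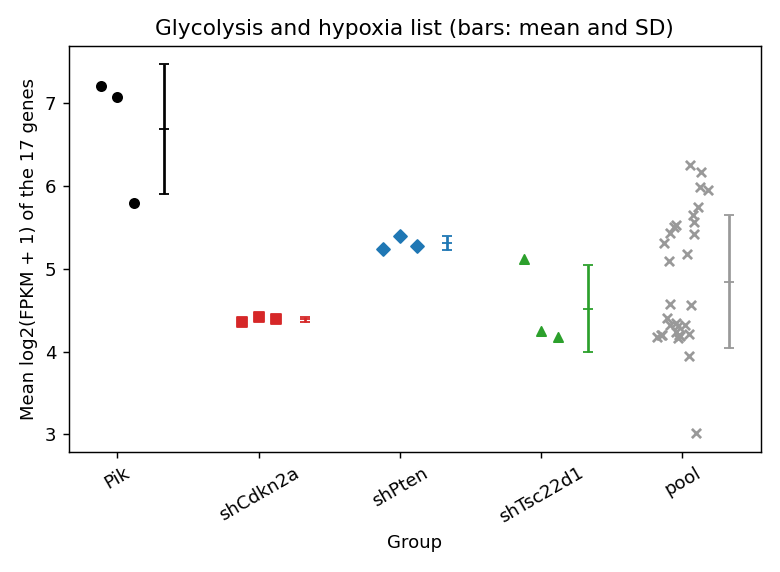
Mean log2(FPKM + 1) of the 17 glycolysis and hypoxia genes in each of the 43 libraries, by group, with the mean and SD of each group as bars. Pik 1 and Pik 2 lie at 7.20 and 7.07, Pik 3 at 5.79, and the 3 libraries labelled shPten at 5.24 to 5.4.

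The libraries labelled shTsc22d1 were of 2 kinds. The library labelled shTsc22d1 1 held keratins as Pik did, and the libraries labelled shTsc22d1 2 and 3 had lymphoid RNA and almost no keratin (Krt8 at 0.170 and 2.79 FPKM). Group means therefore have large SDs. The claudin Cldn3 was at 92.2 ± 158 FPKM against 463 ± 149 in Pik (SD, n = 3 each), a log2 fold change of -5.51 (SE 1.55, limma adjusted p = 0.0325). The lymphocyte GTPase Gimap7 was at 57.0 ± 49.3 FPKM against 0.375 ± 0.282 in Pik (SD, n = 3 each), a log2 fold change of 4.09 (SE 1.21, limma adjusted p = 0.0357). Other large log2 rises with no overlap between groups were in the immune genes Fcrl1 (3.95), Pla2g2d (3.69), Tespa1 (3.49), Tcf7 (3.35), Cd83 (3.31), Stat4 (3.24), Il2rb (2.95) and Ets1 (2.86) and in Ralgps2 (3.06). Other large falls were in Chi3l1 (-5.65), haptoglobin Hp (-5.57), Lcn2 (-5.53), osteopontin Spp1 (-5.27), Cbr2 (-5.22), Irx1 (-5.21), Igfbp2 (-4.93), Mia1 (-4.74) and Egln3 (-4.60). Cdkn2a (-1.77, limma adjusted p = 0.0358) and Cdkn2b (-1.86, adjusted p = 0.0261) fell, Pten (0.99, adjusted p = 0.0308) and Pik3ca (0.81, adjusted p = 0.0331) rose, and Trp53 did not pass (-0.06, adjusted p = 0.757).

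In all, 4721 genes passed between the libraries labelled shTsc22d1 and Pik, 2519 higher and 2202 lower. The groups did not overlap for 24.5% of genes, where chance gives 10% if all are separate tumours. The count was 9723 without the library labelled shTsc22d1 1, and 11 and 3 without the libraries labelled shTsc22d1 2 or 3. Without Pik 1 or Pik 2 it was 27 and 28, and without the 5 libraries that held almost no keratin RNA it was 2. With no filter it was 3144, with all 43 libraries in 1 fit 1, and with the 2 groups alone 0, where limma left 2871 genes at an unadjusted p under 0.05. Of the 120 named genes that passed, 0 passed with limma without each library in turn.

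In the same comparison epithelial and hypoxia lists were lower. Of 14 basal and myoepithelial genes 9 fell, or 14 adjusted over the list alone (median log2 fold change -2.82, camera adjusted p = 0.000421). Of 10 epithelial junction genes 7 fell, or 10 adjusted over the list alone (median -3.28, camera adjusted p = 0.00316), and of 11 luminal progenitor genes 5, or 7 adjusted over the list alone (median -1.86, camera adjusted p = 0.00687). Of 12 immediate early and heat shock genes 6 fell and 1 rose, likewise adjusted over the list alone (median -1.61, camera adjusted p = 0.0106). Of 13 fatty acid synthesis genes 4 fell, or 5 adjusted over the list alone (median -0.65, camera adjusted p = 0.0346). For each of these 5 lists adjusted p = 0.540 with an estimated correlation, and fatty acid synthesis did not pass without Pik 3 (camera adjusted p = 0.0506). Of 17 glycolysis and hypoxia genes 16 fell, likewise adjusted over the list alone (median -2.19, camera adjusted p = 2.41e-09), with Car9 at -3.75 and Bnip3 at -3.09. Pik 1 and Pik 2 stand apart in that list (7.20 and 7.07, against 5.79 in Pik 3), and the library labelled shTsc22d1 1 (5.12) lay inside the range of the keratin-rich pool tumours (5.10 to 6.26). Of 9 squamous keratinization genes 5 fell, or 6 adjusted over the list alone (median -1.87, camera adjusted p = 0.0232). Of 16 p53 target genes 7 fell and 1 rose, likewise adjusted over the list alone (median -0.42, camera adjusted p = 0.0336), with Perp at -4.85. For each of these 3 lists adjusted p = 0.476 with an estimated correlation. Without the library labelled shTsc22d1 1 the squamous and p53 lists did not pass (medians -2.23 and -0.61, camera adjusted p = 0.119 and 0.152). Nor did the p53 list without Pik 2 (median -0.41, camera adjusted p = 0.0578).

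Of 15 hormone-sensing luminal genes 4 fell and 1 rose between the libraries labelled shTsc22d1 and Pik, or 6 and 1 adjusted over the list alone (median log2 fold change -1.96, camera adjusted p = 0.0353, adjusted p = 0.638 with an estimated correlation). That call was lost without the libraries labelled shTsc22d1 2 or 3 (camera adjusted p = 0.0747 and 0.0746) and without Pik 3 (camera adjusted p = 0.0702). Of 12 macrophage genes 4 fell, likewise adjusted over the list alone (median -0.63, camera adjusted p = 0.0346, adjusted p = 0.540 with an estimated correlation), but the list did not pass without the library labelled shTsc22d1 1 (camera adjusted p = 0.188) or Pik 3 (camera adjusted p = 0.280). Lymphocyte and replication lists were higher. All 9 B cell and plasma cell genes rose, likewise adjusted over the list alone (median 5.0), with Cd79a at 5.85. Of 14 T and NK cell genes 8 rose, or 12 adjusted over the list alone (median 3.16), with Lck at 3.63. Of 16 G1-S and replication genes 6 rose, or 7 adjusted over the list alone (median 0.71), with Mcm3 at 1.31. For these 3 lists camera adjusted p = 0.00534, and adjusted p = 0.540 with an estimated correlation. The other 20 lists did not pass (camera adjusted p of 0.0641 to 0.979). Without the 5 libraries that held almost no keratin RNA, 1 library labelled shTsc22d1 was left, and the hormone-sensing luminal list had a median of 0.64. The basal, junction and T and NK cell lists also had medians of the other sign (0.19, 0.19 and -0.09). So did the luminal progenitor (0.10) and immediate early and heat shock lists (0.022), and fatty acid synthesis had a median of -0.018.

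The pool differed from Pik in 34 genes, 13 higher and 21 lower. The groups also differed in their trend with GC content. For this each library's log2 values were taken less the gene means over the keratin-rich libraries of all groups. Their rank correlation with GC content was 0.114 to 0.467 in Pik and -0.583 to 0.158 in the pool. GC content was not regressed out of this comparison, so its share in the calls is unknown. Klkb1, the gene of plasma kallikrein, was at 11.9 ± 7.60 FPKM (SD, n = 31) in the pool and at 0.109 ± 0.0745 (SD, n = 3) in Pik, a log2 fold change of 3.29 (SE 0.50, limma adjusted p = 0.000501). Ndufa4l2 was at 8.60 ± 9.76 FPKM (SD, n = 31) against 183 ± 149 (SD, n = 3) in Pik, a log2 fold change of -4.07 (SE 0.80, limma adjusted p = 0.0171). Pik 1 and Pik 2 held it at 227 and 305 FPKM but Pik 3 at 16.8, under pool tumour 8 (37.0). The other named log2 rises were in Upf3b, a factor of nonsense-mediated decay (1.22), the mitochondrial mt-Nd6 (1.22) and the translation factor Eif5b (0.73). Other named falls were in Nxph4 (-2.78), the glutathione transferase Gstp2 (-2.44), the transcription factor Twist1 (-2.40), Ero1l (-2.33), Cyp26a1 (-2.27), Megf6 (-2.21), Islr (-2.04), the cell cycle inhibitor Cdkn1c (-2.04) and the clock output gene Dbp (-1.99). Ero1l too was high in Pik 1 and Pik 2 (109 and 58.2 FPKM) and at 17.5 in Pik 3, under pool tumour 8 (47.3). None of the genes given in each comparison passed. Their log2 differences were 0.74 for Pten (limma adjusted p = 0.264), 0.68 for Pik3ca (adjusted p = 0.208), -0.22 for Trp53 (adjusted p = 0.730), -0.89 for Tsc22d1 (adjusted p = 0.410), -1.64 for Cdkn2a (adjusted p = 0.236) and -1.66 for Cdkn2b (adjusted p = 0.265).

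Unadjusted p was under 0.05 for 2647 genes between the pool and Pik. The count of 34 was 0 without Pik 1 (923 genes at an unadjusted p under 0.05 with limma), 2 without Pik 2 and 136 without Pik 3. Pik 3 and pool tumour 12 differed by 0.198 (SD over genes of the log2 difference), less than any 2 of the 14 keratin-rich pool tumours (0.320 or more). The count was 13 with a pseudocount of 0.1, 436 after quantile normalization (256 higher and 180 lower), 113 with all 43 libraries in 1 fit, 414 without pool tumours 20 and 21, and 243 without the 17 pool libraries of the second cluster. Of the 14 named genes that passed, 0 passed with limma without each Pik library in turn.

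Among the lists, glycolysis and hypoxia was lower in the pool, with 0 of 17 genes passing over all genes with limma and 16 lower adjusted over the list alone (median log2 fold change -1.84, camera adjusted p = 4.57e-13, adjusted p = 0.716 with an estimated correlation). The glucose transporter Slc2a1 was at -2.48 and aldolase, Aldoa, at -1.82 (limma adjusted p = 0.0746 for both). Pik 1 and Pik 2 stand apart in this list, as given above, and Pik 3 (5.79) lay inside the range of the 14 keratin-rich pool tumours (5.10 to 6.26). In the other lists that passed camera 0 genes passed over all genes with limma, and adjusted p = 0.752 with an estimated correlation for each. Lower were the basal and myoepithelial (median -2.15, camera adjusted p = 0.0005), epithelial junction (median -2.33, camera adjusted p = 0.00351) and luminal progenitor lists (median -1.37, camera adjusted p = 0.0231), with 0 genes adjusted over the list alone. Lower too were squamous keratinization (3 genes adjusted over the list alone, median -1.07, camera adjusted p = 0.00772) and immediate early and heat shock (1 gene adjusted over the list alone, median -1.52, camera adjusted p = 0.00148). So were p53 targets (2 genes adjusted over the list alone, median -0.57, camera adjusted p = 0.0303) and TGF-beta targets (5 genes adjusted over the list alone, median -0.68, camera adjusted p = 0.0413). Higher were T and NK cell (median 2.55, camera adjusted p = 0.0005), B cell and plasma cell (median 4.09, camera adjusted p = 0.000999), G1-S and replication (median 0.62, camera adjusted p = 0.00148) and mitosis (median 0.42, camera adjusted p = 0.0231), with 0 genes adjusted over the list alone. The other 21 lists had camera adjusted p of 0.0653 to 0.970.

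Calls for 4 of these lists were lost without a single Pik library or on another scale, while their medians kept their sign. Mitosis did not pass without Pik 1 (median 0.32, camera adjusted p = 0.0518) or after quantile normalization (median 0.45, camera adjusted p = 0.0599). The p53 targets did not pass without Pik 2 (median -0.52, camera adjusted p = 0.0695), with a pseudocount of 0.1 (median -0.76, camera adjusted p = 0.0501) or after quantile normalization (median -0.54, camera adjusted p = 0.0534). Luminal progenitor genes did not pass without Pik 3 (median -0.83, camera adjusted p = 0.0774). TGF-beta targets did not pass without Pik 3 (median -0.77, camera adjusted p = 0.0590), with a pseudocount of 0.1 (median -0.74, camera adjusted p = 0.0528) or after quantile normalization (median -0.55, camera adjusted p = 0.0819). Without the 17 pool libraries of the second cluster 7 lists passed, of which only 3 were among the 12. The other 9 of the 12 did not pass, namely basal (camera adjusted p = 0.886), junction (0.537), T and NK cell (0.856), B cell (0.977), luminal progenitor (0.977), mitosis (0.183), TGF-beta targets (0.148), G1-S (0.0990) and squamous keratinization (0.0533).

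The groups given single viruses were also compared with each other. The libraries labelled shPten held more keratin RNA and less B cell RNA than shCdkn2a. Krt8 was at 2304 ± 106 against 3.38 ± 2.87 FPKM (SD, n = 3 each), a log2 fold change of 9.27 (limma adjusted p = 0.00320), and Cd79a at 0.393 ± 0.192 against 1000 ± 14 FPKM (SD, n = 3 each), a log2 fold change of -9.50 (limma adjusted p = 0.00261). Krt19 (9.11), Krt5 (8.43), Cnn1 (8.43) and Krt18 (8.34) were also higher, and Iglc2 (-9.49), Iglc3 (-9.10), Cd79b (-8.88) and Glycam1 (-8.60) lower. In all, 9392 genes differed, 4691 higher and 4701 lower, and 4992 with all 43 libraries in 1 fit. These groups did not overlap for 87.2% of genes, where chance gives 10% if all are separate tumours. Of the genes given in each comparison, Cdkn2b (2.90), Cdkn2a (2.54) and Tsc22d1 (2.29) were higher, Pten (-1.06) and Pik3ca (-1.41) lower, and Trp53 did not pass (0.15, limma adjusted p = 0.387). The libraries labelled shTsc22d1 differed from those labelled shPten in 6684 genes, 3467 higher and 3217 lower, with no overlap for 51.6% of genes (chance 10% if all are separate tumours). Here Pik3ca (0.96) and Pten (0.86) were higher, Trp53 (-0.43), Cdkn2a (-1.48) and Cdkn2b (-2.09) lower, and Tsc22d1 did not pass (-1.23, limma adjusted p = 0.0551). Of these 5 only Cdkn2b passed without each library in turn. Gimap3 (5.11), Cd37 (5.05), Btla (4.91), Enpp2 (4.87) and Tbc1d10c (4.80) led the log2 rises, and Krt19 (-7.50), Krt8 (-6.96), Cnn1 (-6.41), Krt5 (-6.37) and Krt18 (-6.21) the falls. That count was 10062, 2044 and 2041 without the libraries labelled shTsc22d1 1, 2 or 3, and 2853, 2967 and 2663 without those labelled shPten 1, 2 or 3. It was 2221 with the 2 groups alone and 298 with all 43 libraries in 1 fit.

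Against shCdkn2a, the libraries labelled shTsc22d1 differed in 16 genes, 4 higher and 12 lower. Col4a2, a collagen chain, was at 40.9 ± 14.9 against 11.7 ± 0.659 FPKM (SD, n = 3 each), a log2 fold change of 1.67 (SE 0.24, limma adjusted p = 0.0365), and Col4a1 and perlecan, Hspg2, rose by 1.5 and 1.20 on the log2 scale. The G protein subunit gene Gnb3 fell by 3.01 on the log2 scale (limma adjusted p = 4.63e-06), Apobec2 fell by 2.40, the lymphocyte repressor Zbtb32 fell by 2.39 and Rilpl2 fell by 0.84. Of these 7 genes 0 passed with limma without each library in turn. Gnb3 passed without each library labelled shTsc22d1, but without any 1 shCdkn2a library it fell below the filter and was not tested. The groups did not overlap for 26.7% of genes, where chance gives 10% if all are separate tumours, and 1457 genes had an unadjusted p under 0.05. None of the genes given in each comparison passed. Their log2 differences were 1.06 for Cdkn2a and for Tsc22d1, 0.80 for Cdkn2b, -0.20 for Pten (limma adjusted p = 0.650), -0.28 for Trp53 and -0.45 for Pik3ca (adjusted p = 0.426 for the other 5). The count was 113 without the library labelled shTsc22d1 1, 1 without shCdkn2a 1, and 0 without shCdkn2a 2 or 3, where limma left 758 and 658 genes at an unadjusted p under 0.05. It was 37 with no filter, 4 with a filter of 5 FPKM, 1 with the 2 groups alone and 0 with all 43 libraries in 1 fit, where limma left 79 genes at an unadjusted p under 0.05. Over the 4 groups of 3, limma's F test called 9350 genes, or 2599 with all 43 libraries in 1 fit.

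The 31 pool tumours fell into 2 clusters of 14 and 17 tumours. In the first, Krt8 was at 650 to 1823 FPKM and Cd79a at 0 to 2.67. In the second, Krt8 was at 0.220 to 103 FPKM and Cd79a at 24.9 to 1097, and Krt18 reached 170, 203 and 389 FPKM in pool tumours 27, 21 and 25, against 547 or more in the first. Cdkn2a ranged from 12.9 to 73.6 FPKM in the first cluster and from 0.706 to 17.7 in the second, Tsc22d1 from 53.7 to 143 and from 12.1 to 31.5, and Pten from 4.59 to 9.99 and from 2.87 to 17.6. The 20 genes with the largest spread over the pool were mostly of 3 kinds. Secretory gland genes were the androgen-binding proteins Abpa, Abpb and Abpg, the prolactin-induced Pip (0.852 to 114610 FPKM, SD 5.15 on the log2 scale), Prol1, Bpifa2, Klk1, Car6, Dcpp1 and Smr3a. Lymphocyte genes were Cd79a, Cd79b, Iglc2, Iglc3 and Ighg2c. Epithelial genes were Krt8, Krt18, Krt19 (0.101 to 2975 FPKM, SD 4.80) and the casein Csn3, and the fibrinogen gene Fgb completed the 20.

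**Figure D3:**
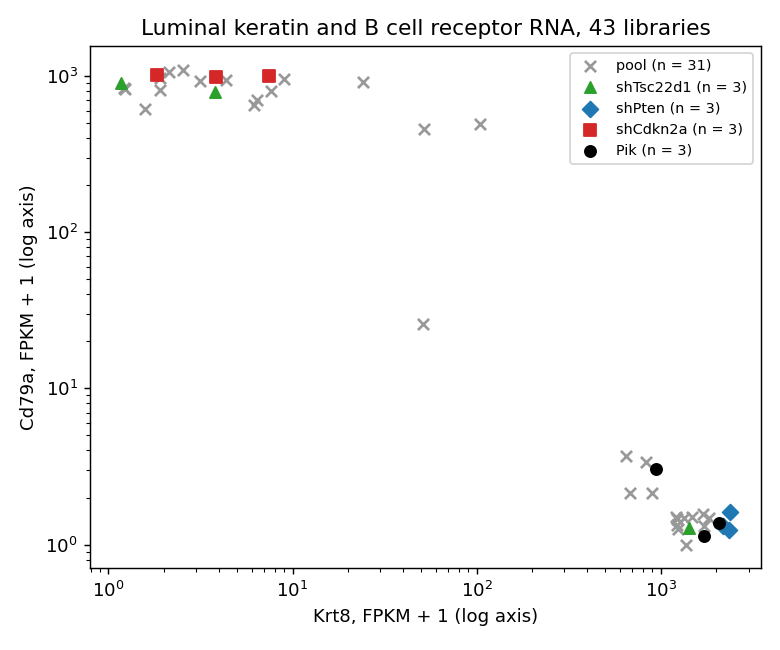
Krt8 against Cd79a as FPKM + 1 (both axes logarithmic) in the 43 libraries, 1 point per library and 1 marker per group. The 3 Pik libraries, the 3 labelled shPten and the library labelled shTsc22d1 1 lie with 14 pool tumours at high Krt8, and the 3 shCdkn2a libraries and the libraries labelled shTsc22d1 2 and 3 lie with the other 17 pool tumours at low Krt8.

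Relations between list scores were computed within each cluster, 16 in all, with 2-sided permutation tests, and 8 passed. In the second cluster (n = 17) fibroblast and matrix genes went with mesenchymal transition genes (r = 0.944, permutation p = 1e-05, the smallest the permutations can give, adjusted p = 0.00016, rho = 0.922, permutation p = 1e-05). Hormone-sensing luminal genes went with basal genes (r = 0.902, permutation p = 3e-05, adjusted p = 0.00024, rho = 0.547, permutation p = 0.0250). Both passed again without the 2 tumours farthest from the median (r = 0.918 and 0.787), though after quantile normalization the former did not. By rank the former passed (permutation adjusted p = 0.00016), but the latter did not (permutation adjusted p = 0.08, rho = 0.339 without the 2 tumours). The other 6 relations did not pass without those tumours. By rank over all tumours of the cluster, mitosis with T and NK cell genes (adjusted p = 0.0221) and junction with mesenchymal transition genes in the first cluster (adjusted p = 0.0450) passed, and the other 4 did not. Of the 6, 2 (interferon with antigen presentation, mitosis with p53 targets) were also lost after quantile normalization. The 6 include, in the second cluster, mitosis with T and NK cell genes (r = 0.870, permutation p = 0.00013, adjusted p = 0.000693, rho = 0.694, permutation p = 0.00276, r = 0.573 without the 2 tumours) and mitosis with p53 targets (r = 0.798, permutation p = 0.00259, adjusted p = 0.00592, rho = 0.498, permutation p = 0.0448, r = 0.490 without the 2). Interferon response went with antigen presentation (r = 0.894, permutation p = 0.00153, adjusted p = 0.00490, rho = 0.297, permutation p = 0.250, r = 0.584 without the 2), and junction genes went against mesenchymal transition genes (r = -0.710, permutation p = 0.0022, adjusted p = 0.00587, rho = -0.578, permutation p = 0.0167, r = -0.372 without the 2). In the first cluster (n = 14) fibroblast and matrix genes went with mesenchymal transition genes (r = 0.904, permutation p = 0.00022, adjusted p = 0.00088, rho = 0.495, permutation p = 0.0757, r = 0.561 without the 2). Junction genes there went against mesenchymal transition genes (r = -0.729, permutation p = 0.00618, adjusted p = 0.0124, rho = -0.684, permutation p = 0.00844, r = -0.437 without the 2).

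Scores of the genes that differed from Pik in shCdkn2a and in the libraries labelled shPten and shTsc22d1 were related to the gene named in the label in the pool, 6 relations in all. A score that rises where that gene is lower gives a negative r. The 2 relations that passed were positive and in the second cluster (n = 17). Cdkn2a gave r = 0.719 (permutation p = 0.0112, adjusted p = 0.0337, rho = 0.0907, permutation p = 0.733) and Pten r = 0.904 (permutation p = 0.00066, adjusted p = 0.00396, rho = 0.466, permutation p = 0.0607). Neither passed without the 2 tumours farthest from the median (r = 0.433 and 0.487), and the Cdkn2a relation did not pass after quantile normalization either (r = 0.559, adjusted p = 0.0632). Tsc22d1 gave r = 0.226 (permutation p = 0.398, adjusted p = 0.415, rho = -0.120, permutation p = 0.646). In the first cluster (n = 14) r was -0.442 for Cdkn2a (permutation p = 0.113, adjusted p = 0.225), 0.337 for Pten (permutation p = 0.239, adjusted p = 0.358) and -0.238 for Tsc22d1 (permutation p = 0.415, adjusted p = 0.415).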

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

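Chosen after the data were seen were the fits without the 5 single-virus libraries that held almost no keratin RNA, without the 17 pool libraries of the second cluster, without pool tumours 20 and 21 and with GC content regressed out, and the list test for shPten with the 2 groups alone. Here shPten and shTsc22d1 name the libraries so labelled. FPKM holds no depth, so how far depth limits the calls of rare transcripts is unknown. For the changes given here the cause was not tested, except that some settings leave fewer libraries. Counts for shCdkn2a against Pik (8984 genes), for shPten against shCdkn2a (9392) and for the F test (9350) stayed within 1.5 times under each alternative run on them except all 43 libraries in 1 fit. Of the named genes that passed against Pik, the robust fit left 136 of 136 (shCdkn2a), 38 of 38 (shPten), 115 of 120 (shTsc22d1) and 14 of 14 (pool). Quantile normalization left 134, 38, 111 and 14 of them, and a pseudocount of 0.1 left 135, 32, 106 and 4.

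With all 43 libraries in 1 fit, limma called 3346 genes for shCdkn2a against Pik, 5 for shPten (279 before), 1 for shTsc22d1 (4721 before) and 113 for the pool (34 before). In the same fit the count was 4992 for shPten against shCdkn2a, 0 for shTsc22d1 against shCdkn2a (16 before, 79 at an unadjusted p under 0.05 in this fit), 298 for shTsc22d1 against shPten (6684 before) and 2599 for the F test. With the 2 groups alone the counts were 1158 for shPten against Pik (278 of the 279 among them) and 0 for shTsc22d1 against Pik (2871 at an unadjusted p under 0.05 with limma). They were 1 for shTsc22d1 against shCdkn2a and 2221 for shTsc22d1 against shPten. No filter gave 3144 genes for shTsc22d1 against Pik and 37 for shTsc22d1 against shCdkn2a, and the filter of 5 FPKM gave 4 for the latter. For the pool the count was 13 with a pseudocount of 0.1, 436 after quantile normalization and 414 without pool tumours 20 and 21, with 34 of the 34 among the last 2.

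The list counts depend on the test. Camera with a preset correlation passed 13, 13, 13 and 12 of 33 lists for shCdkn2a, shPten, shTsc22d1 and the pool against Pik. With an estimated correlation camera passed 0 in each comparison (1, 6, 0 and 1 at an unadjusted p under 0.05), and fry passed 24, 3, 7 and 1, with 13, 3, 3 and 1 of camera's lists among them. Relations between list scores in the pool numbered 8, and 5 after quantile normalization and 2 without the 2 tumours farthest from the median. Scores of the genes that differed in the 3 single-virus groups passed for 2 relations, and for 0 in a permutation test without those tumours (0 at an unadjusted p under 0.05).

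The replicate number as a block gave 108 genes for shPten against Pik and 10 for shTsc22d1 against shCdkn2a. No pairing by number was seen. Over 18 pairs with the same number the correlations were -0.178 to 0.222, against -0.219 to 0.181 for other pairs, and 4 of 12 libraries correlated best with their own number. These correlations cannot exclude that a number marks a shared animal or day.

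Leaving out each library in turn gave 7455 to 8885 genes and 12 to 15 lists for shCdkn2a against Pik. For shPten against Pik it gave 36 to 415 genes and 12 to 13 lists, with 41, 36 and 53 genes without the libraries labelled shPten 1, 2 or 3 and 121 and 135 without Pik 1 or Pik 2. For shTsc22d1 against Pik it gave 3 to 9723 genes and 10 to 17 lists, the 9723 without the library labelled shTsc22d1 1, and 11, 3, 27 and 28 without the libraries labelled shTsc22d1 2 or 3, Pik 1 or Pik 2. For the pool it gave 0 to 136 genes and 11 to 13 lists, with 0 without Pik 1 (923 at an unadjusted p under 0.05 with limma), 2 without Pik 2 and 136 without Pik 3. The ranges were 8124 to 8260 for shPten against shCdkn2a, 2041 to 10062 for shTsc22d1 against shPten and 7619 to 11076 for the F test. For shTsc22d1 against shCdkn2a the range was 0 to 113, with 113 without the library labelled shTsc22d1 1, 1 without shCdkn2a 1 and 0 without shCdkn2a 2 or 3 (758 and 658 at an unadjusted p under 0.05 with limma). Targeted genes passing as lower numbered 1 to 2, the second being Tsc22d1 without the library labelled shTsc22d1 1. Log2 differences that had not passed and changed sign ranged from -0.79 to 0.20 for Cdkn2a and -0.33 to 0.027 for Pik3ca (shPten against Pik), -0.17 to 0.10 for Trp53 (shTsc22d1 against Pik) and -0.39 to 0.17 for Pten (shTsc22d1 against shCdkn2a). Regressing out GC content moved Pik3ca of shPten to 0.045, and the count there was 217.

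Without the 5 libraries with almost no keratin RNA, shPten against Pik gave 1138 genes (278 of the 279 among them) and shTsc22d1 against Pik 2 genes, with 1 library left in the latter group, assumed to vary like the others. Its log2 differences then had the other sign for Tsc22d1 (0.35), Krt18 (0.23), Sox10 (0.21), Csn3 (0.26), Krt5 (0.078), Krt14 (0.27), Cdh1 (0.37), Epcam (0.10), Fads2 (0.031), Hey2 (0.11), Lck (-0.016), Cd3g (-0.12), Cd3e (-0.051), Inpp5d (-0.074) and Ciita (-0.14). Medians of the hormone-sensing luminal (0.64), basal (0.19), junction (0.19) and T and NK cell lists (-0.086) did too, and camera turned the direction of the G1-S list (median 0.036). The medians of luminal progenitor (0.10) and immediate early and heat shock (0.022) also had the other sign, and that of fatty acid synthesis was -0.018. Without the 17 pool libraries of the second cluster the pool gave 243 genes (26 of the 34 among them) and 7 lists (3 of the 12 among them). Tsc22d1 was then at 0.32 and the luminal progenitor list at 0.0052, both of the other sign.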

Other observations

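All tests of explanations in this part, with their marker lists, were chosen after the results they measure were seen. Genes of lymph node structure were abundant in 5 single-virus libraries, the 3 of shCdkn2a and those labelled shTsc22d1 2 and 3. The added list holds 8 genes, of which Cr2 and Fcer2a are also in the B cell list and Glycam1 in the milk list. In the 5 libraries the adhesion ligand Glycam1 was at 394 to 739 FPKM, the follicle chemokine Cxcl13 at 428 to 731, L-selectin, Sell, at 182 to 213, Fcer2a at 153 to 235, Cr2 at 64.3 to 111 and the homing receptor Ccr7 at 55.2 to 76.4. Madcam1 was lower, at 6.30 to 16.7 FPKM, and Chst4 was at 0.0552 to 1.78. The highest Pik values were 0.370 for Glycam1, 2.17 for Cxcl13, 0.648 for Sell, 0.375 for Fcer2a, 0.163 for Cr2, 0.865 for Ccr7, 0.109 for Madcam1 and 0.0856 for Chst4. In the second cluster of the pool Glycam1 ranged from 21.1 to 758 FPKM and Cxcl13 from 22.9 to 1206.

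Genes that salivary and lacrimal glands secrete at high level, a second added list of 8, were high in some libraries only. The salivary genes Bpifa2, Smr3a, Amy1 and Dcpp1 were at 8376, 4107, 2020 and 995 FPKM in the library labelled shTsc22d1 3, and at 100 FPKM or more in 6, 5, 5 and 5 pool tumours. In the other 4 of the 5 lymphoid single-virus libraries Bpifa2 was at 0.935 FPKM or less and Amy1 at 2.09 or less. The androgen-binding proteins Abpa and Abpg and the tear protein Prol1 were at 325, 485 and 426 FPKM in shCdkn2a 2, and at 100 FPKM or more in 8, 6 and 6 pool tumours. Pip was at 2457 FPKM in the library labelled shTsc22d1 3 and at 100 or more in 10 pool tumours. The highest Pik values of the 8 genes were 0.213 (Bpifa2) to 1.64 FPKM (Amy1). Pool tumour 28, in the keratin-rich cluster, held Prol1 at 21098 FPKM and Abpa at 11077.

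The first pattern weighed is lymphoid RNA with almost no keratin RNA in these 5 single-virus libraries. The highest of 6 keratin and junction genes, Epcam, reached 1.67% of its Pik mean, and Krt8 0.0108% to 0.412%. The libraries were picked for almost no keratin RNA, so low keratin in them was fixed in advance. These values show little epithelial RNA relative to Pik. They are no separate test of lymphocytes within a mostly epithelial tumour. Lymph node or other lymphoid tissue in the sample may be a source and stays open, with 7 of the 8 lymph node genes over 10 times the highest Pik library in all 5 (6 of them also at 10 FPKM or more), though Glycam1 and Cxcl13 were already among the largest changes. Knockdown of the labelled gene stays open too: in 5 of the 5 libraries that gene lay inside its range in the 17 pool libraries of the second cluster, which can hold the same hairpins. Low RNA of that gene also need not mean knockdown. Tsc22d1 was lower than in Pik in shCdkn2a as well, whose label names no Tsc22d1 hairpin. In shCdkn2a the hairpin, the RNA of lymphoid cells and the loss of epithelial RNA cannot be told apart, because all 3 libraries are of this kind.

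The second pattern is that libraries outside the pool, Pik 3 among them, lie close to single pool libraries. Among keratin-rich libraries, likeness of separate tumours is argued against, because 2 (Pik 3 with pool tumour 12 at 0.198, and the library labelled shTsc22d1 1 with pool tumour 17 at 0.143) were closer than any 2 keratin-rich pool tumours (0.320). Both pairs go with RNA of 1 tumour in both sets as a candidate explanation, since over the 200 genes most private to the pool tumour they correlated at 0.966 and 0.965, and the next libraries at 0.602 and 0.557. Among lymphoid libraries 4 of 5 were closer than the closest 2 pool libraries of the second cluster (0.195): shCdkn2a 1 to pool 14 (0.193, private genes at 0.934 against 0.768 for the next pool library), shCdkn2a 2 and 3 to pool 15 (0.152 and 0.176, at 0.978 and 0.948 against 0.647) and the library labelled shTsc22d1 2 to pool 5 (0.151, at 0.973 against 0.953), but not shTsc22d1 3 to pool 1 (0.209, at 0.950 against 0.771). These values go with RNA of 1 sample, above all for pool 15. Pool libraries 4 and 5 also reach 0.953, over the genes private to pool 5 only. They are the closest pair (0.195) as well, and whether they are separate samples is not known. Neither value is therefore a sure mark of separate samples, and likeness of separate samples stays open.

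Libraries of 1 group were also close to each other. The 3 libraries labelled shPten lay at most 0.187 apart, under the closest keratin-rich pool pair (0.320). That is also under Pik 3 with pool tumour 12 (0.198) but over the closest pair given above (0.143). RNA of 1 tumour in all 3 may therefore be a cause. Likeness through a shared hairpin stays open, and the SDs and p-values of that group assume 3 separate tumours. In the lymphoid libraries shCdkn2a 2 and 3 lay 0.149 apart. Of 335 genes that differed by over 0.5 on the log2 scale between shCdkn2a 1 and 2, shCdkn2a 3 lay between them for 90.4%, and of 746 such genes the library labelled shTsc22d1 3 lay between pool 1 and shTsc22d1 2 for 94.1%. The same share was 65.4% to 74.3% among the libraries labelled shPten, and the cause was not tested.

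The third pattern is the lower glycolysis and hypoxia list in the libraries labelled shPten. A trend with GC content is argued against as the whole cause, because the list passed with a median of -1.20 once GC content was regressed out. The trend was measured as the rank correlation of GC content with each library's log2 values less the gene means over the keratin-rich libraries. It was 0.604 to 0.624 in the libraries labelled shPten and 0.114 to 0.467 in Pik. High values in 2 Pik tumours may explain the difference, since 16 of 16 other keratin-rich libraries outside shPten lay below Pik 1 and Pik 2. Knockdown of Pten is not seen in the RNA (a log2 difference of 0.13, 95% interval -0.48 to 0.74), and the list leaves it open, because 3 of the 3 libraries lay inside the range of the 14 keratin-rich pool tumours (5.10 to 6.26), which can hold the same hairpin.

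Other splits of the same libraries were counted for each fit. For 3 against 3 there are 10 splits, too few for a share under 0.05. The split by label gave the highest count, 1 of 10 splits, for genes of shCdkn2a against Pik (8984, highest other 3), shPten against Pik (279, highest other 0), shPten against shCdkn2a (9392, highest other 0), shTsc22d1 against shCdkn2a (16, highest other 2) and shTsc22d1 against shPten (6684, highest other 0), and for lists of shPten against Pik (13, highest other 10). For lists of shCdkn2a against Pik 4 of 10 splits gave 13 or more (highest other 14), and for lists of shTsc22d1 against Pik 2 of 10 (13, highest other 13). For genes of shTsc22d1 against Pik 2 of 10 splits gave 4721 or more. The other one, at 5988 genes, puts the library labelled shTsc22d1 1 with Pik 1 and Pik 2, and Pik 3 with the libraries labelled shTsc22d1 2 and 3, so it points to a structure of the samples. Where 100 splits were drawn, the split by label gave the most genes for the F test over the 4 groups of 3 (1 of 100 splits, 9350 against at most 7852). It also did so for the pool against Pik (1 of 100, 34 against at most 28), though that count is 0 without Pik 1, with 923 genes at an unadjusted p under 0.05 with limma. These splits take the libraries as separate tumours. The distances argue against that for Pik 3 with pool tumour 12, and it stays open for the libraries labelled shPten and for shCdkn2a 2 and 3. The splits therefore cannot exclude chance for either count. For lists of the pool against Pik chance is not excluded either (52 of 100 splits gave 12 or more, highest other 23).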
